A study of Arabidopsis thaliana with 48 samples.

How the data were processed

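mRNA of whole Arabidopsis thaliana seedlings was measured by sequencing. The labels give the genotype (wild type, or a mutant named after SNRK1A1 and SNRK1A2, marked kd in the titles), the age (3, 4 or 5 d after germination), light or dark, and glucose at 4 d only. The labels state neither how the mutant was made, nor when light began, nor the glucose dose, nor whether replicates were separate cultures. The p-values therefore measure only the spread between the samples sequenced.

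The deposited tables hold raw read counts per transcript model, as written by featureCounts 1.6.2 from STAR alignments to TAIR10, per the file headers and the labels. Exons were grouped by parent transcript, and a read was counted for every model it overlapped. The authors' labels also name DESeq2, and no normalised values were used here. The exonic length of each transcript model, also given per the file headers as another unit, was used to choose models. Reads were counted without regard to strand, so counts of overlapping antisense genes are uncertain, as are those of near-identical paralogs such as the LHCB1 and RBCS genes.

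The 3 count tables hold 48 columns and 40745 transcript rows for 32678 genes, and 1 column stands in more than one table with identical values. Of these genes, 5883 have more than one transcript row. Because a read can be counted for several models, each gene was represented by its longest exonic model. These models hold 65.2% of all tallied counts. This choice was made after the files were seen, and the sum over models and the first model were run as alternatives. Gene positions are those of TAIR10, and 31912 of the 32678 identifiers matched a locus tag of the reference annotation.

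The titles form 2 series, and the 3 d dark libraries occur in both. Their counts differed between the series by little more than counting error: the chi-square per degree of freedom was 1.04 to 1.06 for columns of the same genotype and number, against 7.14 to 41.4 for different numbers, over genes with at least 50 counts. The 6 repeated columns were therefore taken as second sequencing runs and summed with their partners, which leaves 42 libraries in 14 groups of 3. Separate libraries of the same RNA are not excluded. No column was left out. With 3 libraries per group, the number of libraries limits the precision, and in the shallowest libraries so does counting error.

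Genes were filtered with filterByExpr and normalised with TMM in edgeR 4.0.16 under R 4.3.3, which left 22586 genes. One model with a mean for each of the 14 groups was fitted to all 42 libraries. Each of 25 comparisons (19 between a pair of groups and 6 interactions) was tested with edgeR's robust quasi-likelihood test, 28 residual degrees of freedom and Benjamini-Hochberg adjustment over the tested genes. The threshold was an adjusted p of 0.05, and the biological coefficient of variation was 21.1%. Standard errors of log2 fold changes pool the spread of all 42 libraries, n = 3 per group. CPM take the library total as denominator, unscaled. All glucose libraries belong to the second title series and all untreated 4 d libraries to the first. The design planned a correction through the 3 d dark libraries, but these are taken as runs of the same libraries, which carry no information on separate growth. The glucose comparisons were therefore made directly, the planned corrections are given as alternatives, and a difference between series cannot be told apart from glucose.

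The tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. The 21 lists hold 351 different genes and cover the SnRK1 complex, dark-inducible starvation markers, amino acid catabolism, bZIP C and S1 factors, lipid mobilisation and beta-oxidation, the glyoxylate cycle and gluconeogenesis, seed storage, oleosin and LEA genes, light-harvesting and photosystem genes, Calvin cycle genes, chlorophyll synthesis, light signalling, flavonoid and anthocyanin synthesis, starch and sugar metabolism and transport, autophagy, cytosolic ribosomal proteins, cell cycle and DNA replication, ABA and dehydration response, hypoxia response, senescence and chlorophyll breakdown, root tissue markers, and shoot apex and leaf epidermis markers. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run beside it. Of 525 list tests, 209 passed under camera, 12 of these passed with an estimated correlation, and 236 passed under fry.

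The naming rule took KIN10 and KIN11, up to 3 of the largest rises and falls among called genes of mean log2 CPM of at least 2 whose groups did not overlap, and up to 3 members of each list with the smallest adjusted p. It gave 1867 values over all comparisons. From these, 369 values of 139 genes were picked for the text after their fold changes were seen, and all of them were run under every alternative that applied to their comparison. The report prints part of these, chosen with the alternatives also in view, so the named genes are not a sample of all genes.

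The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, a block for replicate number, a filter of at least 1 CPM in at least 3 libraries, no filter, only the compared groups in the fit, leaving out each library in turn, and the corrections between series. Added after the data were seen were the other transcript models, each sequencing run alone, the fit without 2 doubted dark glucose libraries, and the fit without 3 libraries of high KIN10. The replicate numbers were also checked for pairing. Of 91 pairs of groups, 2 had every correlation of deviations over 0.1, and 1 of these is the genotype pair at 3 d dark.

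The fit was tested on simulated data, with 200 of 22586 genes changed in 1 comparison. edgeR recovered 10% of genes changed 1.5-fold, 50% at 2-fold, 80% at 4-fold and 58% at 0.5-fold, with 4 false calls (3.81% of calls). DESeq2 made 20 false calls (14.4% of calls). A guard set beforehand asked for a higher recovery at 4-fold than the 80% reached. It was replaced, after that result, by guards on bias, false calls and camera. Most misses at 4-fold were genes under 1 CPM, and genes over 4 CPM were recovered at 94.4%.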

Results

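Wild type and the snrk1a1/a2 mutant were each sampled at 3 d in the dark, at 4 d and 5 d in light and in dark, and at 4 d in light and in dark with glucose. Each of these 14 groups held 3 libraries. Totals ran from 4956025 counts (mutant, 5 d light, library 3) to 26126836 (mutant, 3 d dark, library 2), and the 3 d dark totals are sums of 2 columns, taken as sequencing runs of 1 library. SnRK1 is a protein kinase that acts when cellular energy is low, and its catalytic subunits are KIN10 (SnRK1 alpha 1) and KIN11 (SnRK1 alpha 2). Every fold change below is log2 ± the standard error of the 42-library fit, n = 3 per group, mutant over wild type unless another contrast is named.

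The genes named by the mutant's label were measured first. KIN10 (AT3G01090, TAIR10 chromosome 3, 31181 to 34487, 11 exons in the counted model) was not called lower in the mutant in any of the 7 conditions. It stood at 73.6 ± 7.25 CPM (SD, n = 3) in wild type and 113 ± 21.6 CPM in the mutant at 3 d dark, a fold change of 0.49 ± 0.39 (adjusted p = 0.359), which passed with only these 6 libraries in the fit, at 0.49 (adjusted p = 0.0442). In light it was higher in the mutant, by 1.24 ± 0.40 at 4 d (adjusted p = 0.00905) and 1.71 ± 0.40 at 5 d (adjusted p = 0.000528). These calls rest on 3 mutant libraries with 583 (4 d light, 1), 672 (5 d light, 1) and 651 CPM (5 d light, 3), where the highest wild-type library had 228 CPM. Without mutant 4 d light library 1 the 4 d value was 0.25 (adjusted p = 0.556), with only the 6 libraries of the comparison 1.3 (adjusted p = 0.115), and without all 3 libraries the 5 d value was 0.30 (adjusted p = 0.476). Fold changes of KIN10 in the other conditions were 0.18 ± 0.39 at 4 d dark, -0.38 ± 0.39 at 5 d dark, -0.16 ± 0.39 in dark with glucose and 0.68 ± 0.39 in light with glucose, none of them past the threshold. With only 6 libraries in the fit the last of these passed, at 0.70 (adjusted p = 0.0262). KIN11 (AT3G29160, TAIR10 chromosome 3, 11128625 to 11132065, 11 exons in the counted model) was lower in the mutant in light with glucose, at 16.9 ± 0.36 against 33 ± 2.09 CPM (-1.01 ± 0.18, adjusted p = 0.000541). It was also lower at 4 d dark (-0.47 ± 0.17, adjusted p = 0.0205), a call lost without wild-type library 1 (-0.44, adjusted p = 0.0592), wild-type library 3 (-0.41, adjusted p = 0.0708) or mutant library 1 (-0.34, adjusted p = 0.135). KIN11 was -0.21 ± 0.17, -0.30 ± 0.17, -0.22 ± 0.17, -0.31 ± 0.18 and -0.26 ± 0.17 at 3 d dark, 4 d light, 5 d dark, 5 d light and in dark with glucose, none past the threshold. At 5 d light the CPM were 45.6 ± 5.15 in the mutant and 41.2 ± 4.43 in wild type, and the TMM-scaled fold change lies below 0 all the same. Without wild-type library 2 it passed, at -0.44 (adjusted p = 0.0492). Counts cover whole transcripts, so an insertion, an edited allele or a loss at the protein level need not show in them.

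**Figure D1:**
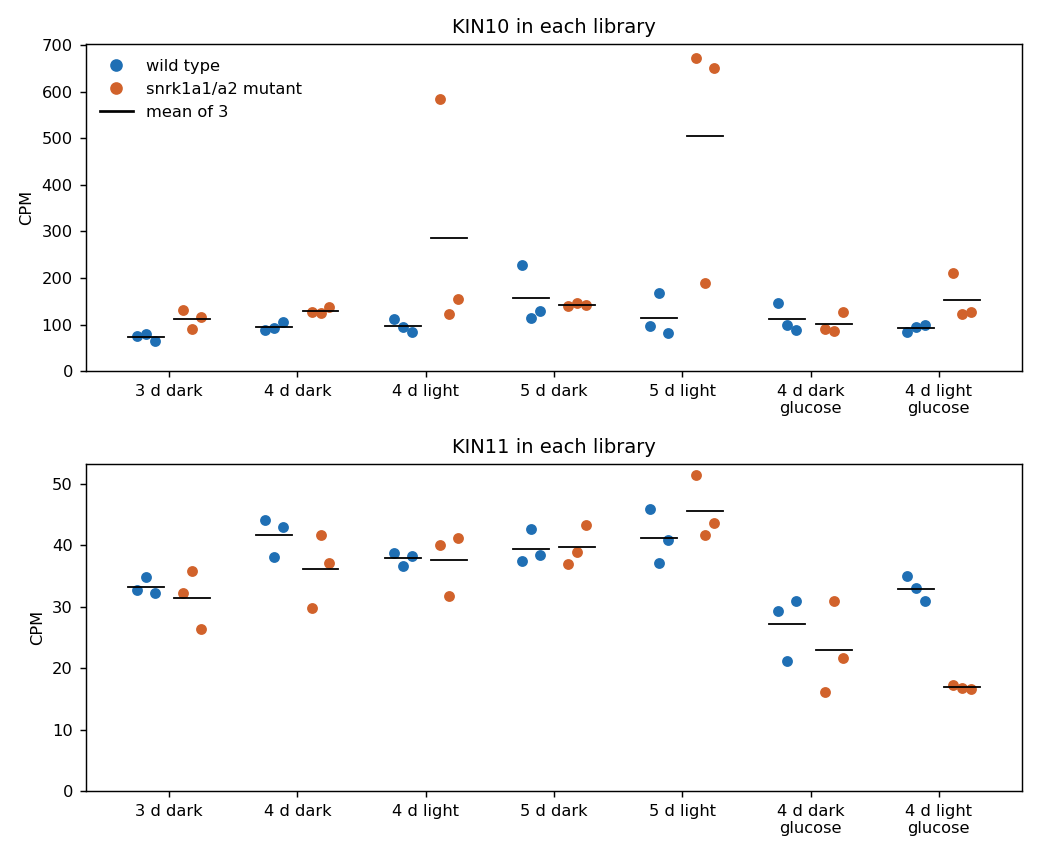
KIN10 and KIN11 in CPM (linear axes) for each of the 42 libraries by condition, with points for libraries and lines for the mean of 3. KIN10 lay above every wild-type library in 3 mutant light libraries, and KIN11 in light with glucose lay lower in all 3 mutant libraries than in all 3 wild-type libraries.

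The first principal component of log2 CPM held 38.8% of the variance and separated the genotypes without glucose. With glucose in the dark, the library labelled wild type 2 lay at 20.3 on this component, beside the libraries labelled mutant 1 and 3 (10.3 and 12.2). The library labelled mutant 2 lay at -36.4, beside the libraries labelled wild type 1 and 3 (-36.6 and -43.2). KIN11 in the library labelled mutant 2 was 30.9 CPM against 16.2 and 21.7 CPM in the other mutant libraries, and 21.2 CPM in the library labelled wild type 2 against 29.3 and 31 CPM. All comparisons keep the labels as given.

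**Figure D2:**
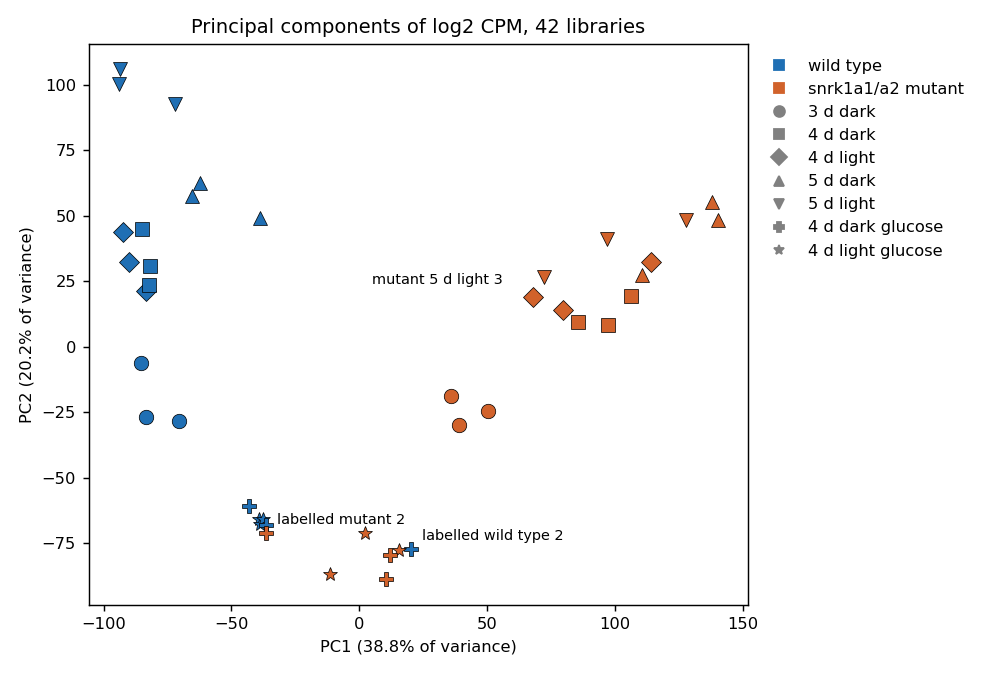
Principal components 1 and 2 of log2 CPM for the 42 libraries, coloured by genotype and shaped by condition. Among the dark glucose libraries, those labelled number 2 lie with the other genotype on the horizontal axis.

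At 3 d in the dark the mutant held fewer transcripts of the photosynthetic apparatus and more of the anthocyanin pathway. Of the 39 light-harvesting and photosystem genes, 39 were lower (39 down adjusted over the list alone, median -1.53, camera adjusted p = 2.21e-16, adjusted p = 0.463 with an estimated correlation). Examples were LHCB1.4 (AT2G34430), a chlorophyll-binding protein, at -4.18 ± 0.74 and LHCA4 (AT3G47470) at -1.97 ± 0.38. Of the 10 Calvin cycle genes, 8 were lower and 2 did not pass (10 down adjusted over the list alone, median -1.33, camera adjusted p = 9.93e-05, adjusted p = 0.463 with an estimated correlation). HEMA1 (AT1G58290), the first committed enzyme of chlorophyll synthesis, was -1.45 ± 0.25 and CAO (AT1G44446) -1.61 ± 0.28. The phytochrome-interacting factor PIF4 (AT2G43010) was -1.86 ± 0.34. Of the 17 flavonoid and anthocyanin genes, 10 were higher and 7 did not pass (11 up adjusted over the list alone, median 1.38, camera adjusted p = 2.52e-05, adjusted p = 0.463 with an estimated correlation). GSTF12 (AT5G17220), needed to load anthocyanin into the vacuole, was 4.62 ± 0.61 and the regulator PAP1 (AT1G56650) 2.38 ± 0.43, while CHS (AT5G13930), chalcone synthase, was 0.85 ± 0.44 and did not pass (adjusted p = 0.142), except with only these 6 libraries in the fit, 0.85 (adjusted p = 0.0301).

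Of the 14 dark-inducible starvation markers, 9 were lower and 5 did not pass (10 down adjusted over the list alone, median -1.04, camera adjusted p = 0.000219, adjusted p = 0.463 with an estimated correlation). TPS11 (AT2G18700) was -1.39 ± 0.22 and EXL2 (AT5G64260) -1.48 ± 0.29, but DIN10 (AT5G20250), a raffinose synthase, was -0.28 ± 0.24 (adjusted p = 0.397). Amino acid catabolism was divided at this age: of the 24 genes, 8 were higher, 7 were lower and 9 did not pass (8 up and 7 down adjusted over the list alone, median -0.08, camera adjusted p = 0.564). The median and the test of that list lie below 0 and its mean above 0. LKR (AT4G33150), which starts lysine breakdown, was -1.89 ± 0.34. Of the 9 bZIP C and S1 factors, 5 were higher, 1 was lower and 3 did not pass (5 up and 1 down adjusted over the list alone, median 0.81, camera adjusted p = 0.0253, adjusted p = 0.463 with an estimated correlation), with bZIP11 (AT4G34590) at 2.62 ± 0.42 and bZIP53 (AT3G62420) at 1.32 ± 0.18. RPL9D (AT4G10450), of the cytosolic ribosome, was 1.03 ± 0.23. Of the 8 hypoxia genes, 5 were higher and 3 did not pass (5 up adjusted over the list alone, median 0.91, camera adjusted p = 0.0103, adjusted p = 0.482 with an estimated correlation), with the haemoglobin gene HB1 (AT2G16060) at 3.90 ± 0.47. The SnRK1 subunits KINB1 (AT5G21170) and KING1 (AT3G48530) were -1.26 ± 0.23 and -1.05 ± 0.23. The largest named rise was BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum, at 8.88 ± 1.16 (adjusted p = 1.01e-06), and WRKY6 (AT1G62300) and ORE1 (AT5G39610), regulators active in leaf senescence, were 2.41 ± 0.23 and 2.41 ± 0.34. Among the falls were the aquaporin TIP2;2 (AT4G17340) at -3.81 ± 0.51 and the transporter UMAMIT17 (AT4G08300) at -3.89 ± 0.73. The other called genes named here had adjusted p of at most 0.000852.

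edgeR's quasi-likelihood test called 7130 of the 22586 tested genes, 3905 higher and 3225 lower, of which 3277 changed at least 2-fold. Groups did not overlap in 49.7% of all tested genes, against 10% by chance. The replicate numbers paired the genotypes weakly here (correlations of 0.139 to 0.19), and a block for the number gave 6783 genes. Fitted on each sequencing run alone, the comparison called 6582 and 6600 genes, 5650 of them in both and in the same direction. Across the 22193 genes tested in both, fold changes correlated at Pearson r = 0.916 and Spearman rho = 0.911. Both runs are taken to read the same libraries.

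At 4 d in the dark the mutant held fewer transcripts of starvation markers, amino acid catabolism and photosynthesis and more of ribosomal proteins. Among 14 dark-inducible starvation markers, 12 were lower and 2 did not pass (13 down adjusted over the list alone, median -2.01, camera adjusted p = 1.9e-06, adjusted p = 0.392 with an estimated correlation). SEN1 (AT4G35770) stood at 129 ± 26.7 CPM in the mutant against 899.7 ± 108 CPM in wild type (SD, n = 3), -3.07 ± 0.33, and the F-box gene KMD4 (AT3G59940) was -2.86 ± 0.33. Among 24 amino acid catabolism genes, 5 were higher, 15 were lower and 4 did not pass (5 up and 15 down adjusted over the list alone, median -1.07, camera adjusted p = 3.46e-05, adjusted p = 0.392 with an estimated correlation). The leucine breakdown genes MCCA (AT1G03090) and MCCB (AT4G34030) were -3.12 ± 0.29 and -2.71 ± 0.20, DIN4 (AT3G13450), a branched-chain keto acid dehydrogenase subunit, was -2.40 ± 0.21, and GDH2 (AT5G07440) was 0.22 ± 0.19 and did not pass (adjusted p = 0.326). Among 39 light-harvesting and photosystem genes, 39 were lower (39 down adjusted over the list alone, median -2.59, camera adjusted p = 1.34e-16, adjusted p = 0.392 with an estimated correlation), with LHCB4.2 (AT3G08940) at -3.64 ± 0.44 and PSBP1 (AT1G06680) at -2.49 ± 0.30. Among 10 Calvin cycle genes, 9 were lower and 1 did not pass (10 down adjusted over the list alone, median -2.01, camera adjusted p = 5.83e-05, adjusted p = 0.392 with an estimated correlation), with GAPA1 (AT3G26650) at -2.85 ± 0.29. Of the 18 cytosolic ribosomal proteins, 18 were higher (18 up adjusted over the list alone, median 1.37, camera adjusted p = 4.79e-10, adjusted p = 0.392 with an estimated correlation), with RPL9D at 2.27 ± 0.24 and RPS6A (AT4G31700) at 1.99 ± 0.23.

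Sucrose export genes SWEET11 (AT3G48740) and SWEET12 (AT5G23660) were -3.36 ± 0.30 and -3.38 ± 0.36, and GPT2 (AT1G61800), a plastid glucose 6-phosphate transporter, was 5.64 ± 0.51. PAP1 was 3.90 ± 0.67 and HB1 5.25 ± 0.50. Of the 12 senescence and chlorophyll breakdown genes, 8 were higher, 1 was lower and 3 did not pass (8 up and 1 down adjusted over the list alone, median 0.75, camera adjusted p = 0.0396, adjusted p = 0.392 with an estimated correlation), with WRKY6 at 3.45 ± 0.24. The factors bZIP11 and bZIP63 (AT5G28770) moved apart, at 3.50 ± 0.44 and -1.22 ± 0.16. Of the 14 lipid mobilisation genes, 5 were higher, 3 were lower and 6 did not pass (5 up and 3 down adjusted over the list alone, median 0.08, camera adjusted p = 0.878), and ACX4 (AT3G51840), a short-chain acyl-CoA oxidase, was -2.35 ± 0.19. The test of that list points down, while its median and mean lie above 0. Of the 15 glyoxylate cycle and gluconeogenesis genes, 3 were higher, 7 were lower and 5 did not pass (3 up and 7 down adjusted over the list alone, median -0.37, camera adjusted p = 0.191). Its peroxisomal malate dehydrogenase PMDH2 (AT5G09660) was -2.42 ± 0.26, and ICL (AT3G21720), isocitrate lyase, was -0.37 ± 0.44 (adjusted p = 0.489). The mitotic cyclin CYCB1;1 (AT4G37490) was 2.31 ± 0.29. The largest named falls were the cell wall gene XTH6 (AT5G65730) at -4.88 ± 0.53 and SCPL13 (AT2G22980) at -5.09 ± 0.60. edgeR called 13091 of the 22586 tested genes, 6658 higher and 6433 lower, 7352 of them by at least 2-fold.

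At 4 d in light Calvin cycle genes had the lowest median of the lists, mutant over wild type. For the 10 Calvin cycle genes, 10 were lower (10 down adjusted over the list alone, median -2.94, camera adjusted p = 4.44e-09, adjusted p = 0.424 with an estimated correlation). GAPA1, the plastid glyceraldehyde 3-phosphate dehydrogenase, stood at 348 ± 100.4 CPM in the mutant against 2623 ± 439 CPM in wild type (SD, n = 3), -3.21 ± 0.30. PRK (AT1G32060), phosphoribulokinase, was -2.89 ± 0.32 and RCA (AT2G39730), Rubisco activase, -2.99 ± 0.34. PETC (AT4G03280), of the cytochrome b6f complex, was -2.06 ± 0.27. For the 14 dark-inducible starvation markers, 1 was higher, 9 were lower and 4 did not pass (1 up and 9 down adjusted over the list alone, median -1.47, camera adjusted p = 0.00194, adjusted p = 0.424 with an estimated correlation), with SEN1 at -2.40 ± 0.32 and DIN10 at -1.69 ± 0.25. DIN4 was -1.98 ± 0.21 and MCCA -2.51 ± 0.28. Among 8 hypoxia genes, 8 were higher (8 up adjusted over the list alone, median 1.64, camera adjusted p = 0.00666, adjusted p = 0.424 with an estimated correlation), with HB1 at 3.94 ± 0.46. Of the 19 cell cycle genes, 2 were higher, 9 were lower and 8 did not pass (2 up and 9 down adjusted over the list alone, median -0.72, camera adjusted p = 0.0434, adjusted p = 0.583 with an estimated correlation). MCM7 (AT4G02060), a replicative helicase subunit, was -1.43 ± 0.27, while MCM2 and MCM5 of the same complex, chosen after their values were seen, stood at 12.6 ± 5.53 and 13.5 ± 2.42 CPM in the mutant against 12.4 ± 2.56 and 13 ± 3.18 CPM in wild type. Of the 15 shoot apex and leaf epidermis markers, 6 were lower and 9 did not pass (6 down adjusted over the list alone, median -0.66, camera adjusted p = 0.0434, adjusted p = 0.424 with an estimated correlation), with KNAT1 (AT4G08150) at -1.11 ± 0.13 and the guard cell regulator FAMA (AT3G24140) at -1.22 ± 0.17. The ABA synthesis gene NCED3 (AT3G14440) was 2.61 ± 0.32. The largest named changes were BIP3 at 8.35 ± 1.15, GPT2 at 6.36 ± 0.68, the aldolase FBA5 (AT4G26530) at -6.07 ± 0.55, XTH6 at -5.80 ± 0.53 and CA1 (AT3G01500), carbonic anhydrase, at -4.76 ± 0.63. edgeR called 12187 genes, 6502 higher and 5685 lower, 6580 by at least 2-fold, and the named genes with a fold change had adjusted p of at most 3.25e-05. KIN10 was raised in mutant library 1 of this group.

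After 5 d in the dark the mutant was lower in starvation markers and shoot apex markers and higher in ribosomal proteins. Across 14 dark-inducible starvation markers, 12 were lower and 2 did not pass (12 down adjusted over the list alone, median -2.02, camera adjusted p = 0.00012, adjusted p = 0.523 with an estimated correlation), with SEN1 at -3.32 ± 0.33 and KMD4 at -3.24 ± 0.33. MCCB was -2.77 ± 0.20. Among 18 cytosolic ribosomal proteins, 18 were higher (18 up adjusted over the list alone, median 1.13, camera adjusted p = 3.41e-06, adjusted p = 0.529 with an estimated correlation), with RPS6A at 1.97 ± 0.23. Among 15 shoot apex and leaf epidermis markers, 1 was higher, 8 were lower and 6 did not pass (1 up and 8 down adjusted over the list alone, median -0.72, camera adjusted p = 0.0282, adjusted p = 0.523 with an estimated correlation). The meristem regulators STM (AT1G62360) and KNAT1 were -2.65 ± 0.28 and -1.77 ± 0.14, with STM at 2.94 ± 0.904 CPM in the mutant and 16 ± 1.2 CPM in wild type (SD, n = 3). Of the 26 autophagy genes, 13 were higher, 7 were lower and 6 did not pass (13 up and 7 down adjusted over the list alone, median 0.32, camera adjusted p = 0.308), with ATG1a (AT3G61960) at 2.64 ± 0.25 and ATG4a (AT2G44140) at -2.40 ± 0.24. Of the 16 ABA genes, 2 were higher, 6 were lower and 8 did not pass (2 up and 6 down adjusted over the list alone, median -0.36, camera adjusted p = 0.337), and RD29B (AT5G52300) was -3.87 ± 0.58. Of the 7 SnRK1 complex genes, 1 was higher, 3 were lower and 3 did not pass (1 up and 3 down adjusted over the list alone, median -0.34, camera adjusted p = 0.246). The light receptor PHYA (AT1G09570) was -1.96 ± 0.22, PIF4 -3.79 ± 0.37 and SWEET11 -4.90 ± 0.32. The largest named changes were 5PTASE11 (AT1G47510), an inositol phosphate phosphatase, at 6.40 ± 0.65, BBX17 (AT1G49130) at -5.32 ± 0.52 and XTH15 (AT4G14130) at -5.28 ± 0.74. edgeR called 13848 of the 22586 tested genes, 6764 higher and 7084 lower, 8251 by at least 2-fold.

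At 5 d in light the lists of photosynthesis genes had the lowest medians, mutant over wild type. Across 10 Calvin cycle genes, 10 were lower (10 down adjusted over the list alone, median -3.22, camera adjusted p = 5.79e-08, adjusted p = 0.363 with an estimated correlation), with GAPA1 at -4.16 ± 0.31. For the 39 light-harvesting and photosystem genes, 39 were lower (39 down adjusted over the list alone, median -2.73, camera adjusted p = 3.97e-16, adjusted p = 0.363 with an estimated correlation), with PETC at -3.11 ± 0.28. The Rubisco small subunit gene RBCS1A (AT1G67090) was -3.15 ± 0.32. Of the 14 dark-inducible starvation markers, 11 were lower and 3 did not pass (11 down adjusted over the list alone, median -1.66, camera adjusted p = 9.09e-05, adjusted p = 0.363 with an estimated correlation), with SEN1 at -3.70 ± 0.34. DIN4 was -2.81 ± 0.21. Cytosolic fructose bisphosphatase cyFBP (AT1G43670) and PMDH2 were -2.50 ± 0.15 and -4.0 ± 0.28. The stomatal genes TMM (AT1G80080) and FAMA were -2.48 ± 0.30 and -1.47 ± 0.19. Of the 14 light signalling genes, 1 was higher, 8 were lower and 5 did not pass (1 up and 9 down adjusted over the list alone, median -0.97, camera adjusted p = 0.0164, adjusted p = 0.363 with an estimated correlation). The replication gene MCM5 (AT2G07690) was 1.68 ± 0.24. Of the 12 root tissue markers, 3 were higher, 2 were lower and 7 did not pass (2 up and 2 down adjusted over the list alone, median 0.50, camera adjusted p = 0.9). The largest named changes were PBS3 (AT5G13320), of salicylic acid synthesis, at 9.12 ± 1.14, the iron-sulfur protein gene NEET (AT5G51720) at -6.15 ± 0.37 and FBA5 at -6.21 ± 0.58. Of the 17 seed genes, 16 were higher and 1 did not pass (16 up adjusted over the list alone, median 5.03, camera adjusted p = 0.0831). These rises were carried largely by mutant library 3, the shallowest of all: OLEO1 (AT4G25140), an oil body protein, was 5.50 ± 1.05 with that library and 1.03 without it (adjusted p = 0.205). edgeR called 13508 of the 22586 tested genes, 7553 higher and 5955 lower, 8384 by at least 2-fold. The median log2 fold change of all tested genes was 0.19 here and 0.16 with RLE size factors. KIN10 was raised in mutant libraries 1 and 3. Library 3 had the most genes with a count (28919) and the highest mitochondrial share (2.21%) of all 42, and library 1 had 26862 genes with a count, against 22906 to 25191 in wild type.

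Across the 5 comparisons without glucose, which share no library, 2599 genes were higher in the mutant in all 5 and 1850 lower in all 5, where independent lists would give 33.2 and 19.1. The 39 light-harvesting and photosystem genes were lower in each of them.

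**Figure D3:**
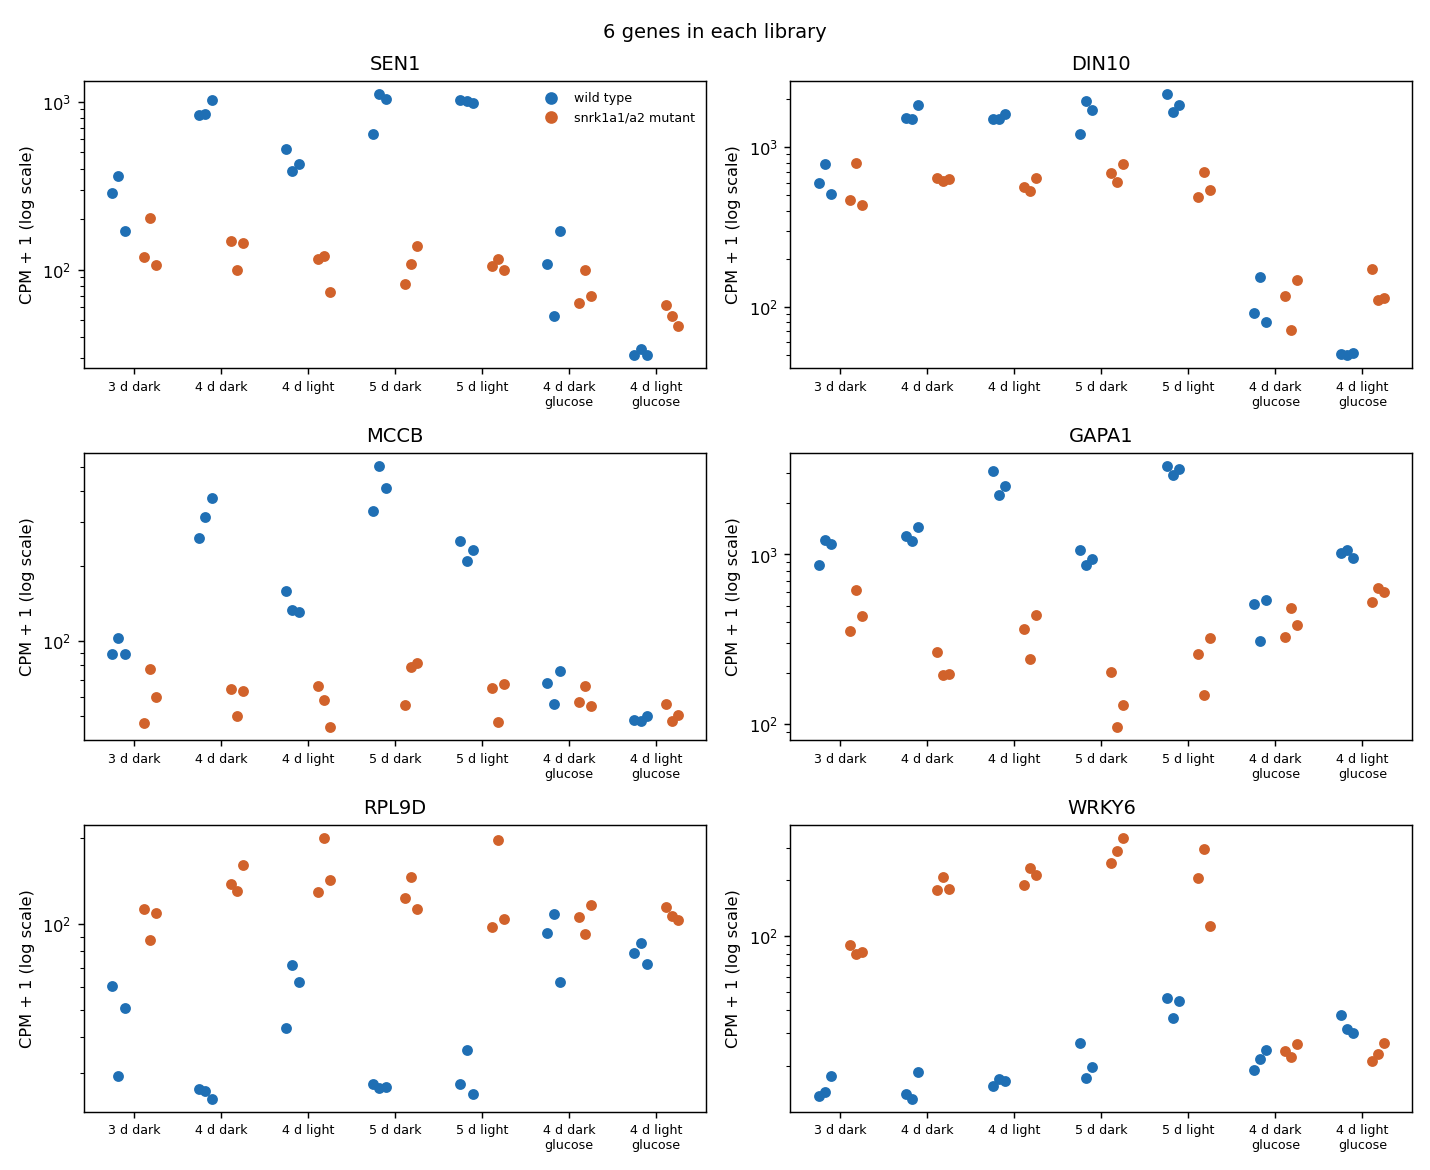
CPM + 1 on log axes of SEN1, DIN10, MCCB, GAPA1, RPL9D and WRKY6 in each library, by condition and genotype. SEN1 at 4 d dark averaged 899.7 CPM in wild type and 129 CPM in the mutant, and 109.5 and 76.2 CPM with glucose.

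Light against dark at 4 d shows what illumination changes in each genotype, light over dark. In wild type NDA1 (AT1G07180), an alternative NADH dehydrogenase of mitochondria, rose by 6.74 ± 0.44, from 0.539 ± 0.0941 to 53.6 ± 9.69 CPM (SD, n = 3), and BAM3 (AT4G17090), a starch-degrading beta-amylase, by 5.74 ± 0.75. Among 17 flavonoid and anthocyanin genes, 15 rose and 2 did not pass (15 up adjusted over the list alone, median 3.06, camera adjusted p = 4.38e-08, adjusted p = 0.171 with an estimated correlation), with CHS at 3.96 ± 0.50 and F3H (AT3G51240) at 3.06 ± 0.54. Of the 10 Calvin cycle genes, 8 rose and 2 did not pass (9 up adjusted over the list alone, median 1.08, camera adjusted p = 0.000173, adjusted p = 0.62 with an estimated correlation), with RCA at 1.70 ± 0.33 and GAPB (AT1G42970) at 1.74 ± 0.34. Across 39 light-harvesting and photosystem genes, 7 rose and 32 did not pass (4 up adjusted over the list alone, median 0.51, camera adjusted p = 0.00369, adjusted p = 0.744 with an estimated correlation), with PETC at 1.22 ± 0.26 and LHCB1.3 (AT1G29930) at -0.11 ± 0.47 (adjusted p = 0.89). For the 18 cytosolic ribosomal proteins, 18 rose (18 up adjusted over the list alone, median 0.80, camera adjusted p = 1.55e-09, adjusted p = 0.558 with an estimated correlation). HEMA1 was 1.46 ± 0.25, and PORA (AT5G54190) and PORB (AT4G27440), reductases of chlorophyll synthesis, were -4.44 ± 0.64 and -2.77 ± 0.49. The photomorphogenesis factor HYH (AT3G17609) was 3.47 ± 0.35, PHYA -1.84 ± 0.21 and ELIP2 (AT4G14690) 4.23 ± 0.59. Among 16 ABA genes, 2 rose, 8 fell and 6 did not pass (2 up and 8 down adjusted over the list alone, median -1.17, camera adjusted p = 9.32e-05, adjusted p = 0.0728 with an estimated correlation), with NCED3 at -3.0 ± 0.32 and ABI2 (AT5G57050) at -2.01 ± 0.22. Among 14 dark-inducible starvation markers, 7 fell and 7 did not pass (7 down adjusted over the list alone, median -0.78, camera adjusted p = 0.00535, adjusted p = 0.65 with an estimated correlation), with BGLU30 (AT3G60140) at -2.78 ± 0.56 and DRM1 (AT1G28330) at -2.39 ± 0.50. MCCB was -1.08 ± 0.19. OLEO3 (AT5G51210) was -4.75 ± 0.59 and the stomatal regulator SPCH (AT5G53210) 1.21 ± 0.30. edgeR called 6297 of the 22586 tested genes, 3259 higher and 3038 lower.

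In the mutant, light at 4 d raised GUN4 (AT3G59400), a chlorophyll synthesis regulator, by 2.01 ± 0.28, HEMA1 by 1.58 ± 0.25, HYH by 2.14 ± 0.33 and LDOX (AT4G22880) of the anthocyanin branch by 3.84 ± 0.64. Of the 39 light-harvesting and photosystem genes, 6 rose and 33 did not pass (24 up adjusted over the list alone, median 0.89, camera adjusted p = 4.94e-20, adjusted p = 0.423 with an estimated correlation). For the 17 flavonoid and anthocyanin genes, 7 rose and 10 did not pass (8 up adjusted over the list alone, median 0.92, camera adjusted p = 1.3e-08, adjusted p = 0.243 with an estimated correlation), and CHS was 0.58 ± 0.45 (adjusted p = 0.553). PHYB (AT2G18790) was -0.87 ± 0.13. edgeR called 535 of the 22586 tested genes, 366 higher and 169 lower. The count was 263 without mutant 4 d light library 2, and 318, 211 and 325 without mutant 4 d dark libraries 1, 2 and 3. Without the libraries of high KIN10 it was 1064, DESeq2 called 847, and 163 passed with only these 6 libraries. In a test of the genotypes' difference, 2074 genes passed (1088 higher and 986 lower). Relative to wild type, NDA1 was -4.63 ± 0.56, BAM3 -5.20 ± 0.93, CSLB03 (AT2G32530) -5.67 ± 0.72 and CHS -3.38 ± 0.65, so the rises were smaller in the mutant. Part of this is a higher dark level, 4.5, 28, 3.1 and 65 CPM in the mutant against 0.54, 2.3, 0.66 and 15 in wild type. The falls of NCED3 and ABI2 were smaller too, at 2.01 ± 0.41 and 1.56 ± 0.30. Across 18 cytosolic ribosomal proteins, 5 were lower and 13 did not pass (17 down adjusted over the list alone, median -0.67, camera adjusted p = 1.56e-07, adjusted p = 0.595 with an estimated correlation). The interaction count was 1078 without wild-type light library 3, 1142 and 1043 without wild-type dark libraries 1 and 3, 1347 without mutant light library 1, and 1346 and 1320 without mutant dark libraries 1 and 2.

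At 5 d in wild type, light raised most antenna and photosystem genes. Among 39 light-harvesting and photosystem genes, 32 rose and 7 did not pass (33 up adjusted over the list alone, median 1.46, camera adjusted p = 7.1e-12, adjusted p = 0.845 with an estimated correlation), with LHCB2.1 (AT2G05100) at 3.70 ± 0.51 and PSAN (AT5G64040) at 2.33 ± 0.35. Among 10 Calvin cycle genes, 9 rose and 1 did not pass (9 up adjusted over the list alone, median 2.03, camera adjusted p = 1.89e-08, adjusted p = 0.423 with an estimated correlation), with RCA at 2.83 ± 0.34. GUN4 was 2.68 ± 0.29. NDA1 rose by 7.81 ± 0.47, BAM3 by 6.0 ± 0.76 and bZIP63 by 1.79 ± 0.16, and the shade gene PIL1 (AT2G46970) was -6.30 ± 0.84. The replication gene MCM2 (AT1G44900) was -1.43 ± 0.29. edgeR called 8002 of the 22586 tested genes, 3727 higher and 4275 lower. Against light at 4 d, with no library shared, 2029 genes rose at both ages and 2016 fell at both, where independent lists would give 538 and 575.

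In the mutant at 5 d, light raised GUN4 by 1.36 ± 0.28, HYH by 1.98 ± 0.33 and UNE10 (AT4G00050) by 2.84 ± 0.35, and lowered PHYB (-1.44 ± 0.14), the leaf polarity gene FIL (AT2G45190) (-1.35 ± 0.20) and CYCB1;1 (-1.92 ± 0.28). Among 17 seed genes, 14 rose and 3 did not pass (15 up adjusted over the list alone, median 5.32, camera adjusted p = 3.05e-05, adjusted p = 0.691 with an estimated correlation), a rise seen mainly in mutant light library 3. EM6 (AT2G40170) was 3.62 ± 0.75, and 1.41 without that library (adjusted p = 0.234). KIN10 was 1.80 ± 0.40, and 0.41 without the libraries of high KIN10 (adjusted p = 0.586). edgeR called 2652 of the 22586 tested genes, 1535 higher and 1117 lower. The count was 1294, 6808 and 529 without mutant light libraries 1, 2 and 3, 806 and 900 without mutant dark libraries 2 and 3, 458 without the libraries of high KIN10, and 8 when only these 6 libraries were fitted. None of the genes named so far here kept its call in that fit (adjusted p 0.113 to 0.281), while their fold changes hardly moved (GUN4 1.37, HYH 1.99, UNE10 2.84, PHYB -1.42). OLEO1, which the filter of that fit removed, was 7.07 ± 1.13, and 2.60 without mutant light library 3, still called. Tested as a difference between genotypes, 6175 genes passed (3652 higher and 2523 lower), 2178 without the libraries of high KIN10 and 3421 with only these 12 libraries in the fit. NDA1 was -6.01 ± 0.60, BAM3 -6.19 ± 0.94, RCA -2.34 ± 0.46 and cyFBP -1.56 ± 0.20 in that test. Part of the NDA1 and BAM3 values is a higher dark level, 3.99 and 47.6 CPM in the mutant against 0.46 and 3.15. RCA and cyFBP lay lower there. For the 10 Calvin cycle genes, 7 were lower and 3 did not pass (8 down adjusted over the list alone, median -1.31, camera adjusted p = 0.000977, adjusted p = 0.813 with an estimated correlation). Among 19 cell cycle genes, 12 were higher, 1 was lower and 6 did not pass (13 up and 2 down adjusted over the list alone, median 1.44, camera adjusted p = 0.000977, adjusted p = 0.813 with an estimated correlation), with MCM5 at 1.79 ± 0.32.

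From 3 d to 4 d in the dark, wild type raised amino acid catabolism and starvation genes, day 4 over day 3. For the 24 amino acid catabolism genes, 16 rose, 1 fell and 7 did not pass (16 up and 1 down adjusted over the list alone, median 1.16, camera adjusted p = 1.03e-14, adjusted p = 0.0194 with an estimated correlation), with BCKDH-E1a (AT1G21400) at 3.08 ± 0.35, MCCB at 1.85 ± 0.19 and ETFQO (AT2G43400) at 1.53 ± 0.16. For the 14 dark-inducible starvation markers, 10 rose and 4 did not pass (13 up adjusted over the list alone, median 1.26, camera adjusted p = 3.07e-09, adjusted p = 0.0968 with an estimated correlation), with ASN1 (AT3G47340), asparagine synthetase, at 3.26 ± 0.50 and SEN1 at 1.82 ± 0.31. Among 26 autophagy genes, 13 rose and 13 did not pass (17 up adjusted over the list alone, median 0.43, camera adjusted p = 1.72e-07, adjusted p = 0.194 with an estimated correlation), with ATG8b (AT4G04620) at 1.70 ± 0.25. Of the 18 cytosolic ribosomal proteins, 16 fell and 2 did not pass (17 down adjusted over the list alone, median -0.79, camera adjusted p = 1.9e-09, adjusted p = 0.257 with an estimated correlation), with RPL27aC (AT1G70600) at -1.12 ± 0.18. CHS was -2.80 ± 0.48 and ELIP2 -4.99 ± 0.61. PPDK (AT4G15530) was 2.07 ± 0.29, the threonine aldolase THA1 (AT1G08630) 4.45 ± 0.64, ORE1 2.53 ± 0.35 and KINB1 1.57 ± 0.23. edgeR called 5455 of the 22586 tested genes, 2737 higher and 2718 lower. The count was 3154 without wild-type 3 d library 3 and 3190 without wild-type 4 d dark library 3.

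In wild type at 4 d light over 3 d dark, NDA1 rose by 7.20 ± 0.43 while PORA and OLEO3 were -5.26 ± 0.66 and -5.65 ± 0.59. LHCB2.1 was 2.12 ± 0.48. GAPA1 was 1.46 ± 0.28. ETFQO was 1.37 ± 0.16. DIN10 was 1.47 ± 0.25 and ASN1 2.32 ± 0.48. For the 19 cell cycle genes, 14 fell and 5 did not pass (16 down adjusted over the list alone, median -0.98, camera adjusted p = 6.37e-05, adjusted p = 0.61 with an estimated correlation), with MCM5 at -1.08 ± 0.20. The beta-oxidation thiolase KAT2 (AT2G33150) was -1.08 ± 0.21. edgeR called 6337 of the 22586 tested genes, 3189 higher and 3148 lower.

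Between 4 d and 5 d in the dark, wild type lost transcripts of the photosynthetic apparatus. For the 39 light-harvesting and photosystem genes, 26 fell and 13 did not pass (37 down adjusted over the list alone, median -1.35, camera adjusted p = 1.92e-27, adjusted p = 0.19 with an estimated correlation), with LHCA1 (AT3G54890) at -2.02 ± 0.42 and LHCB3 (AT5G54270) at -2.22 ± 0.47. RCA was -1.43 ± 0.33. Of the 17 chlorophyll synthesis genes, 9 fell and 8 did not pass (15 down adjusted over the list alone, median -1.05, camera adjusted p = 3.9e-12, adjusted p = 0.176 with an estimated correlation), with HEMA1 at -1.17 ± 0.24. For the 16 ABA genes, 6 rose and 10 did not pass (9 up adjusted over the list alone, median 1.01, camera adjusted p = 3.25e-06, adjusted p = 0.0177 with an estimated correlation), with RD29B at 2.39 ± 0.53. The hypoxia gene HB1 was 2.03 ± 0.44, and 1.39 without wild-type 5 d dark library 1 (adjusted p = 0.0573). The sucrose synthase SUS3 (AT4G02280) was 1.33 ± 0.27 and ATG8b 1.12 ± 0.24. edgeR called 2127 of the 22586 tested genes, 1109 higher and 1018 lower. The count was 743 and 671 without 4 d libraries 1 and 2, and 1260, 1335 and 1293 without 5 d libraries 1, 2 and 3, and 3539 with only these 6 libraries in the fit.

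Between 4 d and 5 d in light, wild type raised senescence genes: among 12 senescence and chlorophyll breakdown genes, 6 rose and 6 did not pass (6 up adjusted over the list alone, median 1.11, camera adjusted p = 1.79e-05, adjusted p = 0.0538 with an estimated correlation). ORE1 was 2.72 ± 0.34, SAG21 (AT4G02380) 1.44 ± 0.27 and WRKY6 1.53 ± 0.23. Across 24 amino acid catabolism genes, 15 rose and 9 did not pass (17 up and 1 down adjusted over the list alone, median 0.73, camera adjusted p = 1.9e-07, adjusted p = 0.16 with an estimated correlation), with BCKDH-E1b1 (AT1G55510) at 1.5 ± 0.20 and GDH2 at 1.2 ± 0.19. SEN1 was 1.26 ± 0.31 and BGLU30 2.22 ± 0.55. Across 19 cell cycle genes, 14 fell and 5 did not pass (1 up and 17 down adjusted over the list alone, median -1.04, camera adjusted p = 6.04e-08, adjusted p = 0.277 with an estimated correlation), with MCM2 at -2.06 ± 0.28. RPL5B (AT5G39740), of the cytosolic ribosome, was -1.10 ± 0.19. edgeR called 6060 of the 22586 tested genes, 3072 higher and 2988 lower.

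The change from 3 d to 4 d was compared between genotypes, mutant response over wild-type response. In the dark the response of catabolic genes was lower in the mutant. Of the 24 amino acid catabolism genes, 12 were lower and 12 did not pass (14 down adjusted over the list alone, median -1.17, camera adjusted p = 2.75e-11, adjusted p = 0.0742 with an estimated correlation), with MCCB at -1.96 ± 0.27. ASN1 was -3.08 ± 0.66 and SEN1 -2.02 ± 0.43. PPDK was -1.95 ± 0.40, KINB1 -1.42 ± 0.32 and SWEET11 -1.87 ± 0.39. Among 18 cytosolic ribosomal proteins, 13 were higher and 5 did not pass (18 up adjusted over the list alone, median 0.89, camera adjusted p = 1.05e-11, adjusted p = 0.417 with an estimated correlation), with RPS6A at 1.39 ± 0.32, and CYCB1;1 was 2.18 ± 0.39. edgeR called 2392 of the 22586 tested genes, 1234 higher and 1158 lower, and with RLE size factors 1569 higher and 878 lower. The count was 1177 and 1092 without wild-type 3 d libraries 1 and 3, 977 without mutant 3 d library 2, 1586 and 1015 without wild-type 4 d dark libraries 1 and 3, 1368 without mutant 4 d dark library 3, and 3785 with only these 12 libraries in the fit. Towards 4 d light the Calvin cycle stood out: across 10 genes, 8 were lower and 2 did not pass (10 down adjusted over the list alone, median -1.63, camera adjusted p = 2.05e-08, adjusted p = 0.385 with an estimated correlation). GAPA1 was -1.87 ± 0.39, bZIP63 -1.72 ± 0.23, PMDH2 -1.81 ± 0.35, SWEET11 -2.16 ± 0.39 and NCED3 2.27 ± 0.41. In this comparison 2055 genes passed, 964 higher and 1091 lower. The count was 1349 without mutant 3 d library 2, 1315 without wild-type 4 d light library 1 and 1269 without mutant 4 d light library 2.

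Glucose at 4 d was compared with no glucose, treated over untreated. In wild type in the dark, glucose lowered starvation markers and raised flavonoid genes. Across 14 dark-inducible starvation markers, 14 fell (14 down adjusted over the list alone, median -2.73, camera adjusted p = 1.24e-18, adjusted p = 0.00425 with an estimated correlation), with DIN10 at -4.20 ± 0.28 and ASN1 at -4.81 ± 0.54. DIN10 stood at 107 ± 39.5 CPM against 1617 ± 182 CPM (SD, n = 3). Among 24 amino acid catabolism genes, 2 rose, 16 fell and 6 did not pass (3 up and 17 down adjusted over the list alone, median -1.84, camera adjusted p = 9.94e-15, adjusted p = 0.00942 with an estimated correlation), with MCCA at -4.09 ± 0.30, DIN4 at -3.22 ± 0.22 and BCAT2 (AT1G10070) at -4.99 ± 0.56. For the 26 autophagy genes, 18 fell and 8 did not pass (20 down adjusted over the list alone, median -0.61, camera adjusted p = 1.39e-07, adjusted p = 0.141 with an estimated correlation), with ATG8e (AT2G45170) at -2.27 ± 0.19. Across 17 flavonoid and anthocyanin genes, 17 rose (17 up adjusted over the list alone, median 5.08, camera adjusted p = 3.54e-19, adjusted p = 0.00425 with an estimated correlation), with F3PH (AT5G07990) at 4.70 ± 0.38. Across 16 ABA genes, 9 rose and 7 did not pass (9 up adjusted over the list alone, median 1.31, camera adjusted p = 0.000246, adjusted p = 0.0348 with an estimated correlation), with KIN1 (AT5G15960), a cold- and ABA-induced gene, at 6.52 ± 0.59 and RD22 (AT5G25610) at 2.99 ± 0.26. Across 39 light-harvesting and photosystem genes, 26 fell and 13 did not pass (38 down adjusted over the list alone, median -1.18, camera adjusted p = 7.31e-08, adjusted p = 0.548 with an estimated correlation), with LHCB1.5 (AT2G34420) at -2.52 ± 0.45. Among 7 SnRK1 complex genes, 3 fell and 4 did not pass (3 down adjusted over the list alone, median -0.28, camera adjusted p = 0.00754, adjusted p = 0.0779 with an estimated correlation), with KINB1 at -3.23 ± 0.24 and KIN11 at -0.87 ± 0.17. This group holds the doubted library labelled wild type 2, where KIN11 was 21.2 CPM against 29.3 and 31 CPM. GPT2 rose by 7.71 ± 0.54 and the starch synthesis gene APL3 (AT4G39210) by 3.38 ± 0.34, while the sugar transporter STP1 (AT1G11260) and bZIP63 were -3.59 ± 0.33 and -2.55 ± 0.17. edgeR called 9692 of the 22586 tested genes, 4973 higher and 4719 lower, and 5561 with a series correction by the 3 d dark columns of the genotype.

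In wild type in light, DIN10 and ASN1 were -5.22 ± 0.29 and -5.59 ± 0.56 with glucose, and GPT2 was 9.06 ± 0.65. Of the 14 dark-inducible starvation markers, 13 fell and 1 did not pass (14 down adjusted over the list alone, median -2.32, camera adjusted p = 2.65e-18, adjusted p = 0.00429 with an estimated correlation). For the 24 amino acid catabolism genes, 3 rose, 15 fell and 6 did not pass (4 up and 16 down adjusted over the list alone, median -1.35, camera adjusted p = 4.07e-10, adjusted p = 0.0299 with an estimated correlation), with ETFQO at -2.18 ± 0.17. Of the 17 flavonoid and anthocyanin genes, 14 rose and 3 did not pass (16 up adjusted over the list alone, median 2.82, camera adjusted p = 7.77e-14, adjusted p = 0.0109 with an estimated correlation). Of the 16 ABA genes, 10 rose and 6 did not pass (11 up adjusted over the list alone, median 2.41, camera adjusted p = 4.85e-09, adjusted p = 0.00209 with an estimated correlation), with NCED3 at 3.54 ± 0.31 and RD22 at 4.0 ± 0.27. GAPA1 was -1.64 ± 0.28. Of the 20 starch and sugar genes, 11 rose, 5 fell and 4 did not pass (11 up and 6 down adjusted over the list alone, median 0.70, camera adjusted p = 0.0355, adjusted p = 0.361 with an estimated correlation). BT1 (AT5G63160), a nutrient-responsive gene, was -5.58 ± 0.34, PCK2 (AT5G65690) -3.65 ± 0.42 and bZIP63 -3.23 ± 0.17. edgeR called 8211 of the 22586 tested genes, 4084 higher and 4127 lower, and 4357 with a series correction by the 3 d dark columns of the genotype. Between dark and light, which share no library, 2624 genes rose in both and 2872 fell in both, against 899 and 862 for independent lists. In each glucose comparison the treatment coincides with the series in the sample titles.

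In the mutant, glucose in the dark lowered senescence genes and raised photosynthesis and cell cycle genes. For the 12 senescence and chlorophyll breakdown genes, 2 rose, 9 fell and 1 did not pass (2 up and 9 down adjusted over the list alone, median -1.42, camera adjusted p = 2.68e-05, adjusted p = 0.0362 with an estimated correlation), with WRKY6 at -3.03 ± 0.23. NBR1 (AT4G24690), an autophagy receptor, was -2.22 ± 0.19. DIN10 was -2.52 ± 0.26. Of the 39 light-harvesting and photosystem genes, 25 rose and 14 did not pass (30 up adjusted over the list alone, median 1.01, camera adjusted p = 1.2e-05, adjusted p = 0.537 with an estimated correlation), with PETE1 (AT1G76100) at 1.4 ± 0.33. Of the 19 cell cycle genes, 16 rose, 1 fell and 2 did not pass (16 up and 1 down adjusted over the list alone, median 1.28, camera adjusted p = 8.61e-07, adjusted p = 0.19 with an estimated correlation), with CDKB1;1 (AT3G54180) at 1.53 ± 0.21. Among 17 flavonoid and anthocyanin genes, 14 rose, 1 fell and 2 did not pass (15 up and 1 down adjusted over the list alone, median 2.95, camera adjusted p = 6.01e-12, adjusted p = 0.0362 with an estimated correlation), with UGT75C1 (AT4G14090) at 2.93 ± 0.27. HB1 was -2.83 ± 0.44, BIP3 -5.46 ± 0.87 and AIG1 (AT1G33960) -5.74 ± 0.63, while LTP3 (AT5G59320) and KIN1 were 6.01 ± 0.46 and 5.40 ± 0.54. MCCB was -0.01 ± 0.19 and did not pass (adjusted p = 0.981). edgeR called 9190 of the 22586 tested genes, 4360 higher and 4830 lower, and 4818 with a series correction by the 3 d dark columns of the genotype. This group holds the doubted library labelled mutant 2.

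In the mutant in light, among 19 cell cycle genes, 17 rose and 2 did not pass (17 up adjusted over the list alone, median 1.65, camera adjusted p = 1.42e-10, adjusted p = 0.115 with an estimated correlation). PCNA2 (AT2G29570) was 1.65 ± 0.22 and CDKB1;1 1.96 ± 0.22. Across 26 autophagy genes, 22 fell and 4 did not pass (23 down adjusted over the list alone, median -0.71, camera adjusted p = 1.14e-09, adjusted p = 0.115 with an estimated correlation), with NBR1 at -1.93 ± 0.18 and ATG8b at -2.35 ± 0.25. PPH (AT5G13800), a chlorophyll-degrading enzyme, was -1.58 ± 0.17. Among 20 starch and sugar genes, 11 rose, 3 fell and 6 did not pass (11 up and 3 down adjusted over the list alone, median 0.73, camera adjusted p = 0.00417, adjusted p = 0.115 with an estimated correlation), with APL3 at 3.56 ± 0.34 and the invertase CWINV1 (AT3G13790) at -1.71 ± 0.16. WRKY6 was -3.26 ± 0.24, AIG1 -6.07 ± 0.63 and KIN11 -1.18 ± 0.18. edgeR called 9709 of the 22586 tested genes, 4470 higher and 5239 lower, and 5606 with a series correction by the 3 d dark columns of the genotype.

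The glucose responses differed between the genotypes, mutant over wild type. In the dark, among 39 light-harvesting and photosystem genes, 39 were higher (39 up adjusted over the list alone, median 2.16, camera adjusted p = 1.37e-15, adjusted p = 0.371 with an estimated correlation), with LHCA4 at 2.88 ± 0.53. Among 14 dark-inducible starvation markers, 12 were higher and 2 did not pass (13 up adjusted over the list alone, median 1.62, camera adjusted p = 2.3e-05, adjusted p = 0.371 with an estimated correlation), with SEN1 at 2.52 ± 0.44. MCCB was 2.52 ± 0.27. For the 18 cytosolic ribosomal proteins, 18 were lower (18 down adjusted over the list alone, median -1.08, camera adjusted p = 4.37e-07, adjusted p = 0.371 with an estimated correlation), with RPL9D at -2.02 ± 0.33. GPT2 was -5.61 ± 0.63, HB1 -5.07 ± 0.62 and WRKY6 -3.30 ± 0.32. edgeR called 8416 genes, 3958 higher and 4458 lower. These dark values keep both doubted libraries, which may inflate them. Without them 5503 passed. A series correction by each genotype's 3 d dark columns gave 3808. In light, of the 10 Calvin cycle genes, 10 were higher (10 up adjusted over the list alone, median 2.05, camera adjusted p = 1.05e-06, adjusted p = 0.349 with an estimated correlation), with GAPA1 at 2.38 ± 0.39. For the 14 dark-inducible starvation markers, 8 were higher and 6 did not pass (9 up adjusted over the list alone, median 1.65, camera adjusted p = 1.31e-05, adjusted p = 0.311 with an estimated correlation), with DIN10 at 3.05 ± 0.35. NCED3 was -2.85 ± 0.41, BT1 4.86 ± 0.43, bZIP63 2.50 ± 0.24, WRKY6 -4.05 ± 0.32 and CYP76C2 (AT2G45570) -6.46 ± 0.78. In light 6740 genes passed, 3126 higher and 3614 lower, and 2713 with that correction.

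With glucose in light the genotypes still differed. The chloroplast regulator GLK1 (AT2G20570) was -1.78 ± 0.24, GUN4 -1.76 ± 0.28 and NDA1 -2.78 ± 0.32 in the mutant, while DIN10 was 1.36 ± 0.25 and ProDH2 (AT5G38710), of proline breakdown, 2.96 ± 0.67. For the 39 light-harvesting and photosystem genes, 4 were lower and 35 did not pass (11 down adjusted over the list alone, median -0.78, camera adjusted p = 3.83e-09, adjusted p = 0.637 with an estimated correlation). RCA was -1.04 ± 0.32, a call lost when any 1 of the 6 libraries was left out (adjusted p from 0.0782 to 0.113), and RBCS1A was -0.59 ± 0.29 (adjusted p = 0.206), or -0.57 (adjusted p = 0.0115) with only these 6 libraries in the fit. Across 18 cytosolic ribosomal proteins, 3 were higher and 15 did not pass (4 up adjusted over the list alone, median 0.40, camera adjusted p = 3.36e-05, adjusted p = 0.637 with an estimated correlation). The amylase BAM5 (AT4G15210) was 5.61 ± 1.04, PMDH2 -1.08 ± 0.25 and BOU (AT5G46800), a mitochondrial carrier, -0.73 ± 0.17. edgeR called 2137 of the 22586 tested genes, 970 higher and 1167 lower. The count was 816, 1305 and 1105 without wild-type libraries 1, 2 and 3, 832 without mutant library 3, and 3774 with only these 6 libraries in the fit.

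With glucose in the dark, edgeR called 0 genes between the libraries as labelled, DESeq2 also called 0, and 532 genes had an unadjusted p under 0.05, fewer than the threshold alone would give. HB1 was 0.19 ± 0.41, GPT2 0.03 ± 0.36, CHS 0.24 ± 0.44 and RBCS1A -0.19 ± 0.29. Across 39 light-harvesting and photosystem genes, none passed (0 adjusted over the list alone, median -0.46, camera adjusted p = 5.4e-09, adjusted p = 0.533 with an estimated correlation). Of the 18 cytosolic ribosomal proteins, none passed (0 adjusted over the list alone, median 0.30, camera adjusted p = 1.16e-10, adjusted p = 0.447 with an estimated correlation). Without the library labelled wild type 2 the count was 26, and without both libraries labelled number 2 it was 1127. In that last fit KIN11 was -0.74 (adjusted p = 0.00683). Deviations of the libraries of the same number were opposed between the genotypes here, with correlations of -0.731 to -0.389.

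**Figure D4:**
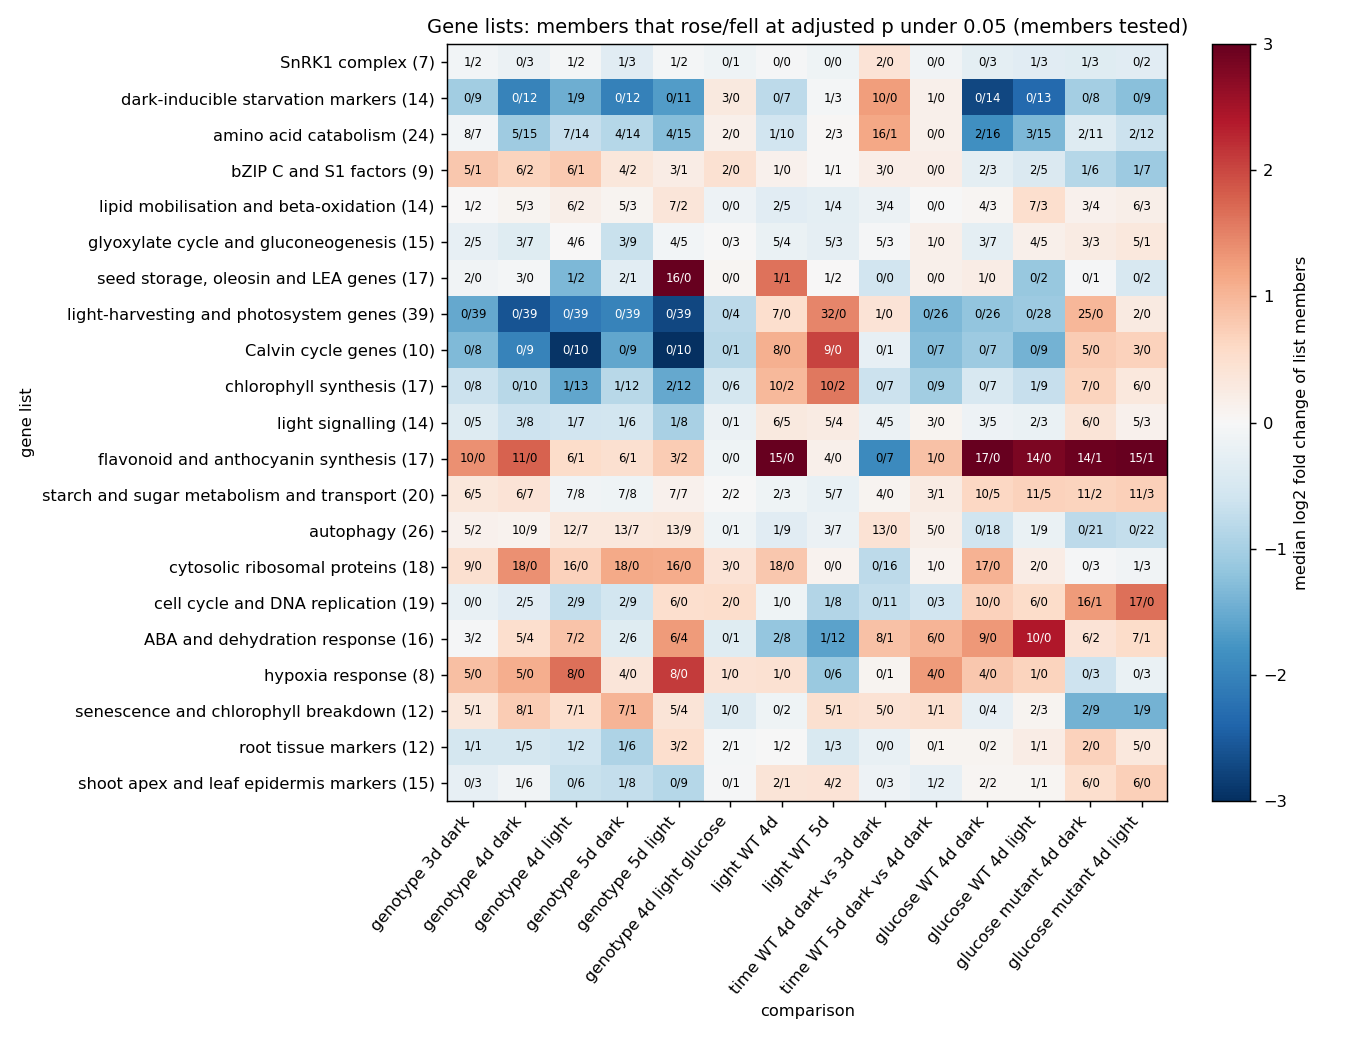
Median log2 fold change (colour) of the 21 gene lists in 14 comparisons, with the members that rose and fell at adjusted p under 0.05 printed in each cell. Light-harvesting and photosystem genes fell 39 of 39 in the 5 genotype comparisons without glucose.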

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

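The tests of exchanged labels, of mixed RNA, of wild-type seedlings in the libraries of high KIN10, of reads from a copy of KIN10 and of dry-seed material were chosen after the results they measure were seen. The others were chosen before. In the dark with glucose, the libraries labelled wild type 2 and mutant 2 lie with the other genotype. On 2137 genes called between the genotypes in light with glucose, scaled to 0 at wild-type libraries 1 and 3 and to 1 at mutant libraries 1 and 3, the library labelled wild type 2 scored 1.02 and the library labelled mutant 2 scored 0.03. RNA of both genotypes mixed in each library would put scores between 0.25 and 0.75, and 0 of 2 lie there, which argues against it. A library size outside the range of the other 4 was found for 2 of 2 (13882925 and 13248515 counts, lowest other 14849891), which met the prediction for library size, but both totals are low while the scores moved in opposite directions, which argues against it. An exchange of the labels of this pair, where 2 of 2 score nearer to the other genotype, may therefore account for the pattern, and no biological explanation was tested.

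KIN10 was high in mutant 4 d light library 1 and mutant 5 d light libraries 1 and 3, at 4.22, 3.55 and 3.43 times the mean of the mutant libraries of their groups without high KIN10 (libraries 2 and 3 at 4 d, library 2 alone at 5 d). Wild-type seedlings mixed into these libraries cannot raise KIN10 above wild type, yet 3 of 3 lie above the highest wild-type library (228 CPM), which argues against it. Reads of a near-identical copy such as KIN11 are argued against too, since the median ratio of KIN11 in the same libraries was 1.1. A move of the other genes towards wild type was tested on a scale from the wild-type to the mutant mean of each group. Scores were 0.84, 0.93 and 0.76, below the other mutant libraries (at least 0.97) in 3 of 3, as in 11.1% of orderings by chance. These libraries enter the mutant mean, and library 2 scored 1.19 at 4 d and 1.31 at 5 d. Library 2 lying further out cannot be told from such a move. Whether KIN10 from a transgene or a released silencing could be behind high KIN10 was not tested.

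Transcripts of seed storage proteins and oleosins were high in mutant 5 d light library 3, where 16 of 17 tested members of the list were highest of all 42 libraries (94.1%). That share restates what drew attention to the library, so dry-seed material mixed into this library stays open. An ABA and dehydration response of the seedlings stays open too, with 4 of 16 members of the ABA list (25%) raised in it, a share that does not decide. A single library cannot speak for its group.

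A test of the difference between the genotypes' responses called genes in each of 6 comparisons, so they are listed here. For light, 2074 genes passed at 4 d and 6175 at 5 d. For time, 2392 passed towards 4 d dark and 2055 towards 4 d light. For glucose, 8416 passed in the dark and 6740 in light. A genotype difference at the starting level can alone give such a call. Each was also fitted on its own 12 libraries, with the genotype labels rearranged within both conditions in 25 ways. For light at 4 d the real grouping gave 2237 genes, the highest other 8331, and 3 of 25 reached the real count. For light at 5 d these values were 3421, 3440 and 2. For time they were 3785, 10023 and 3 towards 4 d dark and 1726, 6636 and 2 towards 4 d light. For glucose they were 8963, 11349 and 3 in the dark and 6600, 6697 and 2 in light. Every other split that reached the real count kept the genotypes of 1 condition whole, so it still holds a genotype difference. Splits that broke the genotypes in both conditions numbered 17, 19, 18, 21, 20 and 18, in the order given, and called no gene. Mixing widens the spread, so these counts cannot decide on a grouping by chance for any of the 6.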

How the results depend on the processing

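The fits without the 2 doubted dark glucose libraries, without the 3 libraries of high KIN10, on single sequencing runs and with other transcript models were chosen after the data were seen, and the others before. Of 245 alternative counts of called genes, 227 stayed within 1.5 times the value given, and of 192 counts that leave out 1 library, 156 did, as did 26 of 26 with a block for the replicate number. 14 of 42 libraries correlate best with their own number. DESeq2 moved light in the mutant at 4 d to 847. Fitting only the compared groups, which estimates the spread from fewer libraries, gave 3774 for genotype 4 d light glucose, 163 and 8 for light in the mutant at 4 d and 5 d, 3421 for its interaction at 5 d, 3539 for time 4 to 5 d dark and 3785 for genotype by time dark. Without the doubted libraries, genotype 4 d dark glucose gave 1127 and genotype by glucose in the dark 5503. Without high KIN10, light in the mutant gave 1064 at 4 d and 458 at 5 d, and the interaction at 5 d 2178. Correcting glucose by the 3 d dark runs of each genotype gave 5561, 4818, 3808 for wild type, mutant and interaction in the dark and 4357, 5606, 2713 in light. Leaving out 1 library moved these counts: genotype 4 d light glucose 816 to 1887, genotype 4 d dark glucose 0 to 26, light in the mutant at 4 d 211 to 618, its interaction at 4 d 1043 to 2209, light in the mutant at 5 d 529 to 6808, time 3 to 4 d dark 3154 to 5835, time 4 to 5 d dark 671 to 1847, genotype by time dark 977 to 3177, genotype by time light 1269 to 2311. Beyond the libraries left out, the cause was not tested. Between the sequencing runs, fold changes of 16679 genes of mean log2 CPM of at least 2 correlated at 0.986.

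The number of the 25 comparisons in which a list passed fell with an estimated correlation: SnRK1 complex 1 to 0, starvation 18 to 2, amino acid catabolism 17 to 3, bZIP C and S1 factors 5 to 0, seed storage 2 to 0, light-harvesting 23 to 0, Calvin cycle 21 to 0, chlorophyll synthesis 17 to 0, light signalling 3 to 0, flavonoid 13 to 3, starch and sugar 3 to 0, autophagy 13 to 0, ribosomal proteins 14 to 0, cell cycle 18 to 0, ABA 14 to 3, hypoxia response 9 to 0, senescence 12 to 1, shoot apex 6 to 0. With fry it moved for SnRK1 complex 1 to 13, bZIP C and S1 factors 5 to 12, lipid mobilisation 0 to 2, glyoxylate cycle 0 to 6, seed storage 2 to 1, light-harvesting 23 to 13, light signalling 3 to 7, starch and sugar 3 to 10, root 0 to 8, shoot apex 6 to 13. Fry tests no contrast with other genes. The cause was not tested.

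Of 343 called values of named genes, 32 lost their call in some alternative, 19 of them on leaving out 1 library, and 0 turned direction. Values not called turned as follows. MCCB with glucose in the mutant in the dark (log2 -0.00700) was 0.0116 with no filter, 0.0246 and 0.0542 with corrections between series by the mean of the genotypes and by each genotype, and -0.114 to 0.0588 on leaving out 1 library, above 0 without untreated library 1 (0.0551) or 3 (0.0395) or treated library 1 (0.0287) or 3. On leaving out 1 library, ICL at 3 d dark ranged from -0.714 to 0.0969 (highest without wild type 1) and KIN10 at 5 d dark from -0.586 to 0.0320 (highest without wild type 1). In genotype 4 d dark glucose the ranges were KIN10 -0.344 to 0.129 (highest without wild type 1), GPT2 -0.0928 to 0.206 (below 0 also without wild type 1, -0.0545, and wild type 3, -0.0333), RBCS1A -0.452 to 0.0400 (highest without wild type 1), CHS -0.00594 to 0.371 (lowest without mutant 1) and HB1 -0.295 to 0.499 (lowest without mutant 3). The cause was not tested. Depth limits genes under 1 CPM: in simulated data 2 of 10 of these were recovered at 4-fold.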

Other observations

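No test in this part was chosen after its result was seen, and the genes of the first paragraph were chosen with their values in view. At 4 d dark the mutant was lower in the light receptor PHYA (-1.44 ± 0.21), the phytochrome-interacting factor PIF4 (-3.34 ± 0.36) and HEMA1 (-2.48 ± 0.26), of chlorophyll synthesis (log2 ± SE, n = 3 per group). Of the 14 light signalling genes, 3 were higher, 8 were lower and 3 did not pass (3 up and 8 down adjusted over the list alone, median -0.62, camera adjusted p = 0.0965). Of the 20 starch and sugar genes, 6 were higher, 7 were lower and 7 did not pass (6 up and 8 down adjusted over the list alone, median 0.42, camera adjusted p = 0.81). The test of that last list points down, while its median and mean lie above 0. In the dark at 5 d, of the 12 root tissue markers, 1 was higher, 6 were lower and 5 did not pass (1 up and 6 down adjusted over the list alone, median -0.92, camera adjusted p = 0.256), and CYCB1;1 was 3.10 ± 0.31. In wild type at 5 d, light lowered ABA genes: of the 16 ABA genes, 1 rose, 12 fell and 3 did not pass (1 up and 12 down adjusted over the list alone, median -1.61, camera adjusted p = 0.000413, adjusted p = 0.132 with an estimated correlation). SAG21 was 1.79 ± 0.28 there. In the mutant in light, glucose changed KIN1 by 5.47 ± 0.55 and F3PH (AT5G07990), of flavonoid synthesis, by 4.0 ± 0.34.

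A hypothesis tested here is that glucose lowers the genes that are lower in the mutant, as it would if low sugar raised them through SnRK1. The comparisons share no library: glucose in wild type in light at 4 d, and genotype at 5 d dark. Of the genes that fell with glucose, 2697 were lower in the mutant, against 1294 for independent lists, a ratio of 2.08, and 396 were higher, against 1236. Genes that rose with glucose and were higher in the mutant numbered 1946, against 1223. The ratio is consistent with the hypothesis, which had asked for over 1.5, but genes that respond to growth rate could give such an overlap as well, and this was not tested.

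Each comparison between a pair of groups was also fitted on its 6 libraries alone, with the group labels rearranged in 10 ways, which are too few for a share under 0.05. In 18 comparisons no other split called a gene. Each other split mixes the real groups, so a large difference between them widens its spread and leaves few calls. The lack of calls there therefore does not speak for the real groupings. The real grouping was 1 of 10 as large. Between genotypes it called 7282 (3 d dark), 13607 (4 d dark), 9989 (4 d light), 12500 (5 d dark) and 9489 (5 d light). It called 3774 in light with glucose and 6480 at 3 d dark in the second series. For light it called 8442 (wild type 4 d), 163 (mutant 4 d) and 8081 (wild type 5 d). Over time in wild type it called 6559 and 6697 from 3 d to 4 d dark and light. From 4 d to 5 d it called 3539 in dark and 7809 in light. For glucose it called 9556 (wild type) and 8751 (mutant) in the dark, and 10689 and 6583 in light. For light mutant 5 d it called 8, the highest other 419, and 2 of 10 were as large. For genotype 4 d dark glucose it called 0, the highest other, which exchanges the libraries numbered 2, 5762, and 10 of 10 were as large.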
